A study of Mimachlamys nobilis with 6 samples.

How the data were processed

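RNA sequencing was done on adductor muscle of QN Orange scallops (Mimachlamys nobilis, a bivalve) aged 1 year, per the labels. 3 libraries came from a control group without RNA interference (RNAi) and 3 from a group with RNAi against VPS29. Per the labels' protocols, muscle was frozen in liquid nitrogen, total RNA of each tank was isolated with TRIzol, and libraries followed standard Illumina protocols. No label says whether a library held 1 animal or several, or whether the libraries of a group came from different tanks. The p-values therefore measure the spread between these libraries, which may be partly technical.

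The deposited values are FPKM (fragments scaled by gene length and library size) for 30231 gene IDs in each library, made by the authors and used as deposited. HISAT2 2.0.4 and HTSeq 0.9.1 are named per the submitters' processing notes, which give no role, order or parameter for them. The genome build, the annotation and the strand setting are not given in the sources used here. The files do not pair the gene IDs with gene names, and give neither gene lengths nor read totals.

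Whole reads were recovered from the steps of the FPKM values. An FPKM is the reads divided by gene length and library size, up to a fixed factor, so a single length and 6 library sizes must turn all values of a gene into whole numbers. This held for 23403 of the 23408 genes above 0 in any library (99.98%), within 0.01 read and a relative error of 1e-09. The other 5 genes were left out of every step on reads. On simulated reads the same steps returned the exact reads for 93.2% of genes. Reads of a gene that share a common factor cannot be told from reads smaller by that factor, so such genes get too few reads and too short a length. Of 1935 genes above 0 in all 6 libraries whose deposited values had been jittered, 0 were given a length. Genes above 0 in fewer libraries were not tried. With few values a length can be met by accident, so part of the 99.98% was assured beforehand. The library sizes found behind the FPKM were 18171608, 30519170 and 15953438 reads in control replicates 1, 2 and 3, and 24434309, 34767399 and 31086511 reads in RNAi replicates 1, 2 and 3. They were 0.74 to 1.67 times the recovered read totals. Divided by the median-of-ratios size factor of the recovered reads, they had a spread of 2.9%. The divisors of the FPKM thus followed a scaling by size factors rather than the read totals, a step that no source used here describes.

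The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) on log2(FPKM + 1), with the group as the only term. It was run on the 9715 genes with at least 1 FPKM in at least 3 of the 6 libraries. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Single values were compared between groups by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. Libraries were compared by Pearson correlation of log2(FPKM + 1) and by principal components over the tested genes. Same-group libraries were checked for duplicates with a chi-square per gene on the recovered reads. The limma steps were tested on simulated data with 200 changed genes in each of 20 runs. They called 16.0% of genes changed by 1 on the log2 scale, 70.5% of those changed by 2 and 89.4% of those changed by 3, with 5.55 false calls per run. Simulated genes varied independently, and only genes of higher control level were changed. The real libraries share axes of variation that the simulation lacks, so these rates may not hold for them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the recovery of reads, the descriptions and the figures.

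Groups, tests, alternatives and the rule for named genes were set before the data were examined. By that rule, genes past the threshold, with non-overlapping groups and at least 5 FPKM in the larger group mean, would be named by largest change. If fewer than 20 qualified, the list was to be filled with the smallest unadjusted p among genes with non-overlapping groups and that level. As no ID has a name, the 2 IDs with the largest rise and the 2 with the largest fall in that list are described. Some IDs consist of an ordinary word and a running number. Genes with such an ID are given in the text by their length inferred from the FPKM steps, and by ID and length in the plots. The 10 genes with the highest mean FPKM describe the tissue.

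The alternatives were leaving out each library in turn, a replicate block, other filters and pseudocounts, TMM, quantile and TPM scaling, eBayes without trend and robust, array weights, and other thresholds. After the data had been seen, voom on the recovered reads, scaling to the total of recovered reads and the share of reads in the 10 most abundant genes as a covariate were added, as was the count at an unadjusted p under 0.05. The VPS29 transcript, retromer members and gene lists for endosomal sorting, carotenoid and lipid handling, muscle, metabolism, stress, immunity and other tissues were planned. They need gene names and are not analysed here.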

Results

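The transcriptome of the adductor muscle, the muscle that closes the shell, was profiled in 3 control libraries and 3 libraries with RNAi against VPS29 from QN Orange scallops. VPS29 is a subunit of retromer, the complex that returns membrane proteins from endosomes, and RNAi lowers the transcript of a targeted gene. Recovered reads totalled 18709500, 20709193 and 21546124 in control replicates 1, 2 and 3, and 16150427, 20826088 and 19807300 in RNAi replicates 1, 2 and 3. Between 18130 and 20112 of 30231 gene IDs had a value above 0, and 9172 to 9523 reached 1 FPKM. The 3 pairs within each group differed by more than the sampling of reads, with a median chi-square per gene of 3.88 to 8.60, so none was a copy of another. As the files do not pair gene IDs with names, the VPS29 transcript is not given here, and the knockdown itself was not checked.

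A single gene held the largest share of reads in this muscle. This gene, with an inferred length of 1275 bases, took 38.0% ± 9.96 of recovered reads in the control libraries and 26.5% ± 6.91 in the RNAi libraries (SD, n = 3 each). Its share ranged from 22.48% in RNAi replicate 3 (95% Wilson interval 22.46% to 22.50%) to 48.70% in control replicate 3 (48.68% to 48.72%). These intervals cover counting error only. The difference in share gave p = 0.2 in an exact two-sided permutation test, whose smallest possible value with 3 against 3 is 0.1. Its level was 321220 ± 182400 FPKM in control and 132310 ± 40340 FPKM in RNAi muscle, a log2 difference of -1.15 ± 0.48 (SE) with an adjusted p of 0.279 in limma. The log2 difference was -0.73 without control replicate 3, -0.48 under TPM and -0.52 under total recovered reads. With the read share of the 10 most abundant genes as a covariate, which removes part of this gene's own difference, it was -0.29. Quantile normalization sets the top gene of every library to the same value, so it gives 0 here by construction. With array weights it was -1.30 and passed, at an adjusted p of 0.0439 in limma (0.0439 to 1 over the alternatives). Array weights called 1236 genes between the groups but 2750 under another grouping of the same libraries, so passing with them says little about RNAi. The 10 most abundant genes together held 54.3% ± 11.5 of control reads and 42.5% ± 6.4 of RNAi reads (SD, n = 3 each, exact permutation p = 0.2).

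Of those 10 genes, 9 had a lower mean in the RNAi libraries on the log2 scale. Among the 9, evm.TU.Contig1462.6 was only at -0.022 ± 0.58 (SE), and its mean FPKM was higher in RNAi muscle (8763.5 against 7626.5). The median difference of the 10 genes was -0.79. This median was -0.47 without control replicate 3, -0.16 under total recovered reads, -0.12 under TPM and -0.11 under quantile normalization, which evens out the highest values. It was -0.20 with the read share of these same genes as a covariate, a fit that removes part of their own difference. None passed the main test, their smallest adjusted p in limma being 0.279. With array weights evm.TU.Contig744.2 also passed, at -1.61 with an adjusted p of 0.0397 in limma (0.0397 to 0.853 over the alternatives). The difference was -1.02 ± 0.51 for evm.TU.Contig745.1, -0.94 ± 0.50 for evm.TU.Contig744.1 and -1.14 ± 0.51 for evm.TU.Contig744.2 (SE). Without control replicate 3 these were -0.54, -0.44 and -0.81. In the same order they were -0.35, -0.27 and -0.46 under TPM, and -0.043, 0.025 and -0.21 with the covariate. Array weights made them larger, at -1.28, -1.05 and -1.61. The groups did not overlap for 1 of the 10, evm.TU.Contig731.36, at 10604 ± 2679 FPKM in control and 6594 ± 1043 FPKM in RNAi muscle (SD, n = 3 each), with an adjusted p of 0.318. Its log2 difference of -0.66 went to 0.008 under TPM and -0.03 under total recovered reads. In 5 of the 10, namely the most abundant gene, evm.TU.Contig744.1, evm.TU.Contig744.2, evm.TU.Contig745.1 and evm.TU.Contig745.2, control replicate 3 was the highest library and RNAi replicate 2 the lowest. The sign depended on the scaling, as 5 of the 10 were below 0 under TPM, 6 under total recovered reads, 6 under quantile normalization and 8 under TMM. TPM and total recovered reads shift all genes upward, moving the median of all tested genes from -0.05 to 0.49 and 0.42. Relative to that median, 8 of the 10 were lower in the main test, 8 under TPM and 7 under total recovered reads, and the median of the 10 minus that of all genes was -0.74, -0.61 and -0.58.

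**Figure D1:**
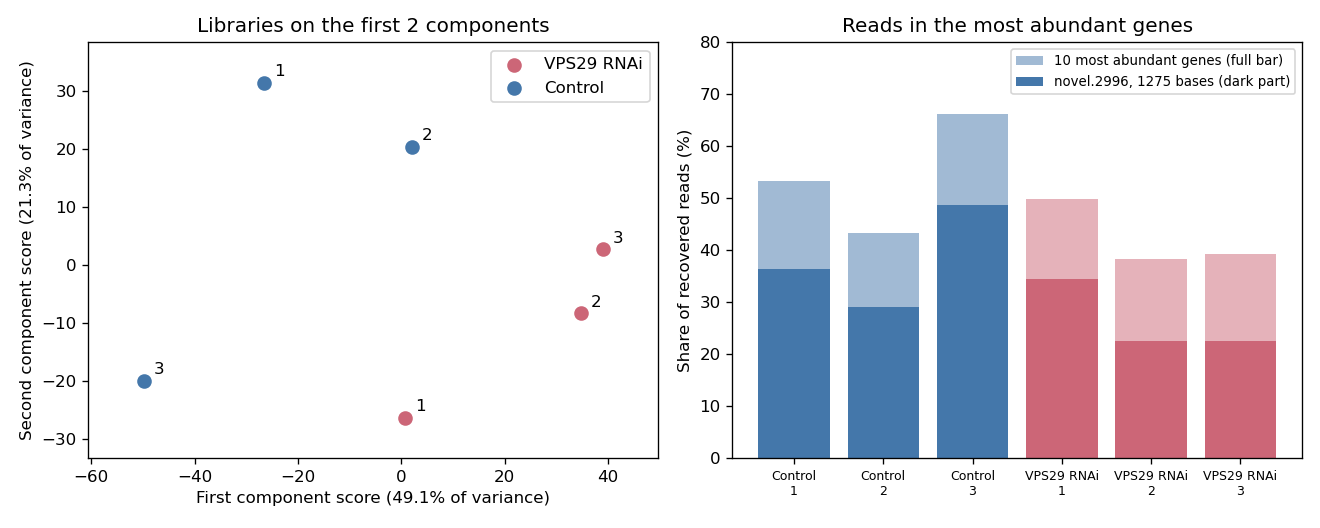
Libraries of the control and RNAi groups on the first 2 principal components of log2(FPKM + 1), which held 49.1% and 21.3% of the variance, beside the percentage of recovered reads in the 10 most abundant genes per library. Control replicate 3 had the highest share, 66.2%, and RNAi replicate 2 the lowest, 38.3%.

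The comparison of VPS29 RNAi with control muscle asked which transcripts differ after RNAi. The gene evm.TU.Contig902.18 had 9.61 ± 7.45 FPKM in control and 138 ± 35.2 FPKM in RNAi muscle, a log2 difference of 4.05 ± 0.62. For evm.TU.Contig1226.8 the levels were 12.8 ± 6.41 and 254 ± 193 FPKM, a log2 difference of 3.97 ± 0.60. In the other direction, a gene with an inferred length of 293 bases went from 33.0 ± 14.8 FPKM in control to 2.64 ± 1.09 FPKM in RNAi muscle, a log2 difference of -3.15 ± 0.42. A gene with an inferred length of 666 bases had 12.1 ± 8.73 FPKM in control and 0.433 ± 0.713 FPKM in RNAi muscle, a log2 difference of -3.10 ± 0.49, and RNAi replicate 1 was listed at 0. With this low level the difference depended on the pseudocount, at -5.28 with 0.1 FPKM, -6.88 with 0.01 FPKM and -6.17 in voom. Levels are means ± SD with n = 3 per group and log2 differences are given ± SE. With 1 library left out, the log2 difference ran from 3.26 to 4.60 for evm.TU.Contig902.18, 3.38 to 4.61 for evm.TU.Contig1226.8, -3.60 to -2.88 for the gene of 293 bases and -3.49 to -2.60 for the gene of 666 bases. The 4 genes were chosen for non-overlapping groups, so leaving out 1 library could not change their sign. These fits therefore show only how far the size of the difference varied. For evm.TU.Contig902.18 the lowest values were 3.26 without control replicate 3 and 2.82 with the read-share covariate.

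None of these 4 genes passed the threshold in the main test, though all 4 passed under TPM, total recovered reads and array weights. The adjusted p depends on all genes tested, and TPM and total recovered reads shift all genes upward. Under TPM the gene of 293 bases went from -3.15 ± 0.42 to -2.73 ± 0.51 (SE), yet its adjusted p in limma fell to 0.0324. For evm.TU.Contig1226.8 the difference grew, from 3.97 ± 0.60 to 4.67 ± 0.61 (SE). Passing under a scaling is thus not in itself stronger evidence. Array weights called more genes under another grouping of the libraries. The adjusted p of the 4 genes in the main limma test was 0.0685 for the gene of 293 bases. It was 0.0804 for evm.TU.Contig902.18, evm.TU.Contig1226.8 and the gene of 666 bases. The 4 genes belong to a list of 20 genes, 10 higher and 10 lower, which was filled by smallest p among genes with non-overlapping groups because no gene passed, and in which the adjusted p ran from 0.0685 to 0.0804.

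Across the 9715 genes tested, limma called 0 at an adjusted p under 0.05, and 45 at an adjusted p under 0.1, of which 22 were higher and 23 lower in RNAi muscle. At an unadjusted p under 0.05 there were 1654 genes (17.0%), 751 higher and 903 lower, where chance alone gives 486. With voom on the recovered reads, 0 genes passed and 1660 had an unadjusted p under 0.05. Groups did not overlap for 2201 genes (22.7%, against 10% by chance), 1018 higher and 1183 lower. Another grouping of the same libraries, control replicates 1 and 3 with RNAi replicate 1 against the rest, separated more genes, 2646 (27.2%), and had 1990 genes at an unadjusted p under 0.05. A difference of at least 2-fold was seen for 287 genes in the higher and 386 in the lower direction, and the median size of the log2 difference was 0.32. The count of 0 became 161 under TPM (149 higher, 12 lower), 105 under scaling to total recovered reads (94 higher, 11 lower), 1236 with array weights (0 to 1074 with 1 library left out), 6 with a filter of 5 FPKM and 6 without RNAi replicate 1. The 751 higher and 903 lower became 2103 and 122 under TPM, and 2017 and 134 under total recovered reads. The 1654 became 914 without RNAi replicate 2 and 1039 without RNAi replicate 3.

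**Figure D2:**
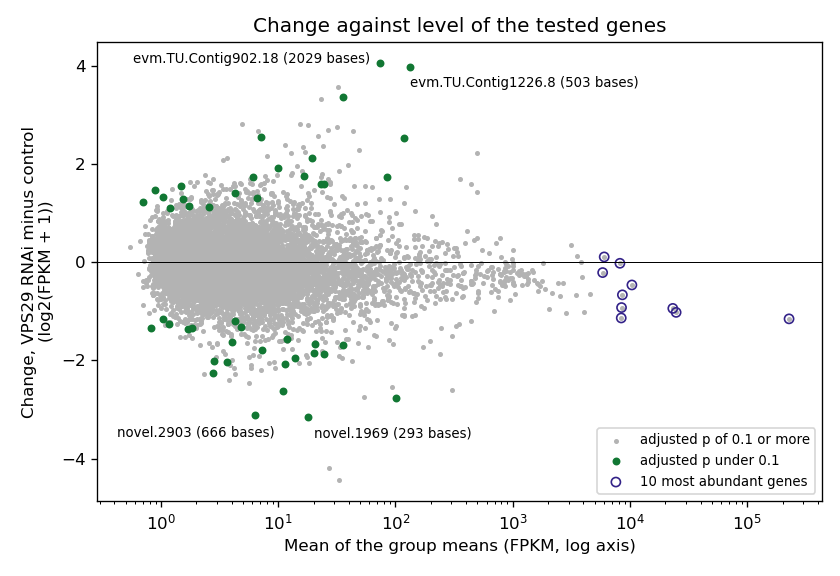
Log2 difference between RNAi and control means, on log2(FPKM + 1), against the mean of the group means in FPKM on a log axis, 1 point per tested gene (9715). Filled green points are the 45 genes with an adjusted p under 0.1 in limma, and open circles the 10 most abundant genes, 9 of which lie below 0 (5 under TPM). Of these 9, evm.TU.Contig1462.6 lies only at -0.022.

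**Figure D3:**
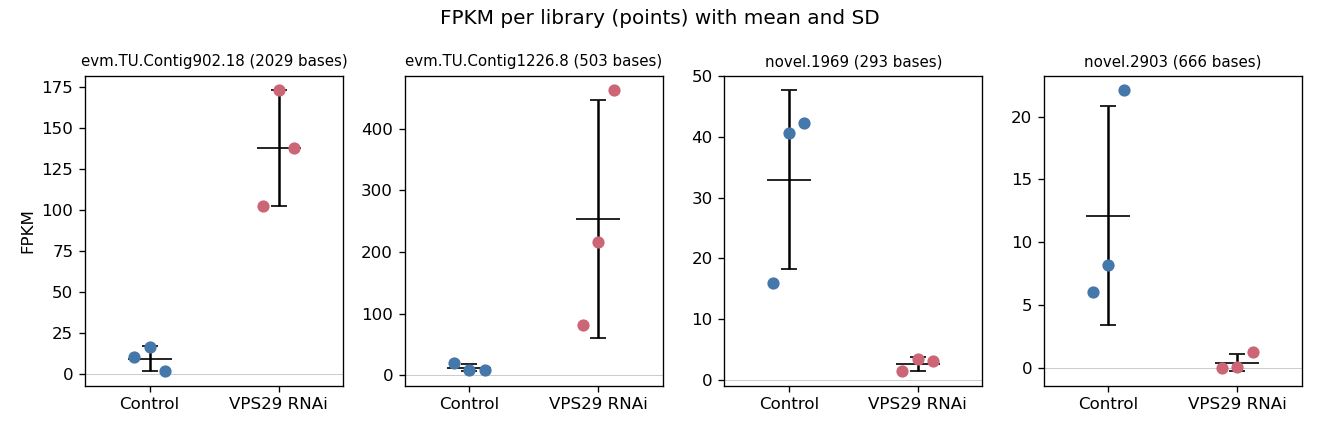
FPKM of the 4 described genes on linear axes, with a point for each of the 3 control and 3 RNAi libraries, a horizontal line for the group mean and a bar for ± 1 SD. The genes were chosen among those whose groups do not overlap, and their group means run from 0.433 to 254 FPKM.

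Libraries of the same group resembled each other slightly more than libraries of different groups. Pearson's r of log2(FPKM + 1) across genes ranged from 0.849 to 0.965, with a mean of 0.926 among control libraries, 0.943 among RNAi libraries and 0.904 between the groups. The within-group mean exceeded the between-group mean by 0.0297 (exact permutation p = 0.1, the smallest possible). This p shows only that no other split exceeded the groups, by however little. The difference was nearly as large for control replicates 1 and 3 with RNAi replicate 1 against the rest. Scores on the first principal component were -26.6, 2.0 and -49.9 for control replicates 1, 2 and 3, and 0.8, 34.7 and 39.0 for RNAi replicates 1, 2 and 3. The groups thus overlapped on this axis (exact two-sided permutation p = 0.2).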

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

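Voom, scaling to total recovered reads, the covariate and the count at an unadjusted p under 0.05 were chosen after the data had been seen. The count past an adjusted p of 0.05, 0 in limma, stayed at 0 in 15 of 21 alternatives, with 1654 genes at an unadjusted p under 0.05 (voom 1660). Among the 15, asking for at least 2-fold as well could only give 0. The adjusted count was 6 (5 FPKM filter), 161 (TPM), 105 (total reads) and 1236 (array weights). It was 45 at an adjusted p under 0.1, and 0 to 6 with 1 library left out (6 without RNAi replicate 1). The unadjusted count was 914 (without RNAi replicate 2) to 2189 (without control replicate 2), 1039 without RNAi replicate 3 and 3350 with array weights. Filters also changed the number of genes tested. The count was 716 of 3570 genes with the 5 FPKM filter and 2441 of 23408 without a filter, against 1654 of 9715. TPM and total reads moved the median log2 difference from -0.05 to 0.49 and 0.42, and the share of higher genes at an unadjusted p under 0.05 from 45.4% to 94.5% and 93.8%. The excess of within-group correlation was 0.0171 to 0.0488 with 1 library left out.

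Same-numbered libraries did not deviate together (r = -0.04, 0.29 and -0.33, none best with its own number), so numbers were not taken as pairs. The replicate block gave 0 genes, and 1511 at an unadjusted p under 0.05.

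Of 266 values for 14 genes, 232 kept direction (1 was 0 by construction) and side of the threshold, 16 became significant and 18 changed sign, all in abundant genes. Chosen for non-overlapping groups, the 4 described genes could not change sign with 1 library left out. They passed under TPM, total reads and array weights, with the limits given above (adjusted p over alternatives 0.0133 to 0.3). So did evm.TU.Contig1226.8 without RNAi replicate 1 (0.0487) and the gene of 293 bases with the 5 FPKM filter (0.041). For evm.TU.Contig1462.6 the log2 difference was -0.46 to 0.67 with 1 library left out. It was 0.042 (TMM), 0.84 (quantile), 0.65 (TPM), 0.17 (array weights) and 0.61 (total reads). For the gene of 273 bases it was -0.19 to 0.57 with 1 library left out. With the covariate it was -0.19, and 0.025 for evm.TU.Contig744.1. For evm.TU.Contig1357.4 it was 0.25 (quantile), 0.46 (TPM) and 0.42 (total reads). Under TPM, evm.TU.Contig251.4 was at 0.21 (total reads 0.17) and evm.TU.Contig731.36 at 0.008. Beyond the scaling shifts, the cause was not tested. Alternatives for the VPS29 transcript and gene lists were not run. A count of 0 allows up to 3 reads.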

Other observations

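The splits for the count past an adjusted p of 0.05, the test without the most abundant genes, the test of RNAi on the first component, the neighbour test, the relation of the component to read share and the genes with reads in 1 group were chosen after the results had been seen.

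Chosen after their values were seen, 2 genes had at least 10 reads in every library of one group and 0 in the other. A gene with an inferred length of 1117 bases had 58, 52 and 65 reads in RNAi replicates 1, 2 and 3 and 0 in each control library (1.78 ± 0.40 FPKM, SD, n = 3). The RNAi mean was 42.8 times a floor of 3 reads over the control group. A gene with an inferred length of 428 bases had 27, 21 and 60 reads in control replicates 1, 2 and 3 and 0 in each RNAi library (4.62 ± 3.73 FPKM, SD, n = 3), at least 59.5-fold lower in RNAi muscle. Among the 9 other splits of the libraries, the highest count of such genes was also 2.

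The excess of small p-values was weighed against regrouping of the libraries. For 1654 genes at an unadjusted p under 0.05, 2 of the 10 splits gave as many, and the highest other, 1990, set control replicates 1 and 3 with RNAi replicate 1 against the rest. For the count of 0 past an adjusted p of 0.05 the splits decide nothing, since any split gives at least 0 (10 of the 10 did, the highest other being 1). With array weights, 1236 genes passed, 3 of the 10 splits gave as many and the highest other was 2750, so this count points to a structure of the libraries beyond the groups. Of the explanations, 10 splits are too few for a share under 0.05, while 1 library with a large weight may carry the array-weights count, since RNAi replicate 2 had a weight of 4.48 and 0 genes passed without it, though 0 also passed without control replicate 1 or RNAi replicate 3, and 318, 47 and 1074 without control replicate 2, control replicate 3 and RNAi replicate 1. The effect of VPS29 RNAi remains open.

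The first component, 49.1% of the variance, followed the share of reads in the 10 most abundant genes over the 6 libraries (Pearson r = -0.96, exact permutation p = 0.0028; Spearman rho = -0.94, exact permutation p = 0.017; 1 relation computed). Without control replicate 3 and RNAi replicate 2, r was -0.91. Thinning each library to the smallest size behind the FPKM kept 45.9% to 100% of reads and left 12417 to 13000 genes with at least 10 reads. The scores then correlated at r = 0.99998 with those before, which argues against sampling noise from unequal sizes behind the FPKM. This thinning did not even out the read totals, so it cannot exclude a difference in sequencing depth. Without the 971 most abundant genes, the scores correlated at r = 0.99981 with those of all tested genes. The axis was thus also present in the other genes. As most tested genes stayed in, the scores could hardly move, so this does not decide whether the abundant genes' values shape it. The other genes also kept the same library divisors, so an effect of the abundant genes through the scaling was not tested. Whether VPS29 RNAi sets this axis cannot be told apart from the spread between libraries (exact permutation p = 0.2), and differences in the dissected tissue or in RNA quality, which were not tested, may also do so.

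More abundant genes tended to be lower in the RNAi libraries, with a Spearman correlation across genes of -0.163 between mean level and log2 difference, genes not being independent replicates. Of the 10 splits, 2 gave a correlation as far from 0, the highest other size being 0.171, and 10 splits are too few for a share under 0.05.

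Neighbouring gene IDs on a contig had correlated log2 differences, r = 0.223 over 3045 pairs. This was not specific to the RNAi contrast, as 5 of the 10 splits gave a correlation as high, up to 0.272.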
